A study of Mus musculus with 15 samples.

How the data were processed

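The submitters made libraries from 1 to 1.5 ng of RNA with the NuGEN Ovation RNA-seq V2 kit, after checking that its integrity number was above 7. Sequencing used a pair of Illumina instrument models, and which library ran on which is not given in the sources used here. Per the submitters' notes, reads were aligned to GRCm38 with STAR 2.4.2a, counted per gene with HTSeq and normalized and tested with DESeq2. Strand, annotation release and counting mode are not given in the sources used here. The signal values of the 3 tables, as deposited by the authors, are reads divided by a size factor for each library, made separately for each table. Dividing each column by its step, the value of 1 read, gave back whole reads for 100% of values within 1e-06, and a count of 3 reads, the floor used for depth, equals 2.16 to 4.81 normalized reads. PCR copies are counted as reads, so such floors cover counting error only. The tables list 15788, 15793 and 14932 genes, each with at least 2 reads, and 99.6% of the symbols of the IP table matched GENCODE M21, 473 of them through older symbols. The P37 and P56 wild-type IP libraries are in both the IP and the genotype table; each test used values of 1 table.

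The comparisons, 35 gene lists, named-gene rule and alternatives were fixed before the data were examined, apart from alternatives said below to be chosen after seeing the data. Counts had been assumed; since the tables held normalized values, the planned fallback was used: limma-trend (3.58.1, R 4.3.3) on log2(value + 1), over genes with a value of at least 10 in as many libraries as the smaller group, with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for genes are limma's unless edgeR (4.0.16) or DESeq2 (1.42.0) is named; those tools ran on the recovered reads of the genotype and drug tables. They were not run on IP against input, because the step of the P37 input column lies so close to 1 that the check for recovered reads does not apply to it, although its values came back whole like the others. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry, and adjusted over the lists of a comparison. With an estimated correlation camera takes its degrees of freedom from the libraries, which are few here. A list can then hardly pass in IP against input, where failing that test does not tell whether a list changed. The genotype comparison had more libraries, so a failure there is less readily set aside. Library scores were compared with exact two-sided permutation tests. In each comparison the genes named are Mecp2, Cck and Grm5, up to 10 rises and 10 falls that passed with a mean of at least 50 and separated groups, the 5 smallest p-values under the same conditions where fewer passed, and up to 4 members of a list with the smallest p.

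The labels state that knockouts and wild types were littermates and give 1 library of each genotype at each age, without tying litters to ages. Same-age libraries were read as pairs in a further fit with age as a block, fixed with the others beforehand. Their correlations after removal of group means were 0.171 at P37, 0.0578 at P41, 0.0644 at P50 and 0.132 at P56, and not all were above the 0.1 set as a criterion; the reading rests on the label text and was adopted after the counts of both fits had been seen. The unblocked fit is the one reported unless the block is named. A test of each fit on simulated data with 200 changed genes recovered 81% of 4-fold and 23.5% of 2-fold changes in IP against input (5 false calls), 88.9% and 50% for genotype (2 false calls) and 56.1% and 3.03% for CTEP (3 false calls).

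The relation to length used GENCODE M21 transcript and genomic lengths. Genotype splits were all 35 divisions of the 8 libraries into 4 and 4, and random lists were 10000 draws matched over 20 bins of expression.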

Results

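Rett syndrome follows from loss of MeCP2, a nuclear protein that binds methylated DNA, and mice without Mecp2 are its usual animal model. The series followed what such a loss, and a drug against the glutamate receptor mGluR5, did to the RNA on ribosomes of hippocampal CA1 neurons. Ribosomes bearing an EGFP-tagged L10a protein, made under control of the cholecystokinin gene Cck, were pulled down from hippocampus. Their RNA was sequenced (translating ribosome affinity purification, IP libraries). There were 15 libraries. Wild-type and Mecp2-knockout IP libraries numbered 4 each, 1 per genotype at postnatal day 37 (P37), P41, P50 and P56. Another 2 wild-type input libraries from unpurified hippocampal RNA matched the P37 and P56 IP libraries. A further 5 knockout IP libraries came from mice given CTEP, a negative allosteric modulator of mGluR5 (3 libraries, 2 at P57 and 1 at P60), or vehicle (2 libraries, at P57 and P60). CTEP was given at 0.4 mg/kg every 48 h. Library totals ran from 3987746 reads (P56 input) to 11464745 in the IP and input table, from 6686077 to 11464752 in the genotype table and from 7853821 (P60 vehicle) to 16526396 (P57 CTEP) in the drug table. How many mice gave 1 library was not stated in the labels, so p-values measure the spread between these libraries.

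The IP and input libraries were compared to learn whose transcripts the Cck line captured. Genes of CA1 pyramidal neurons were enriched in IP. Pou3f1, a transcription factor gene of CA1 neurons, stood at 2804 ± 203 in IP and 339.9 ± 40.3 in input (normalized reads, mean ± SD, n = 2 libraries each). Wfs1, which encodes the endoplasmic reticulum protein wolframin, stood at 7918 ± 2520 and 1173 ± 174. Of the 8 CA1 markers tested, 7 were higher in IP and none was lower, with a median log2 difference of 1.76. Cck itself was higher by 1.92 ± 0.21 on the log2 scale (SE). The deepest losses from IP were transcripts made inside mitochondria, away from the tagged ribosomes. All 7 mitochondrially encoded genes tested were lower, by a median of -5.22. Of these mt-Cytb, the cytochrome b gene, stood at 225 ± 56.3 in IP and 9806 ± 3886 in input. Medians below 0 were also found for markers of glia, blood vessels, choroid plexus and inhibitory neurons, as shown in the plot of IP and input by gene list. Camera called these lists with a preset correlation, and none passed with an estimated one (adjusted p = 0.406 with an estimated correlation).

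In limma's moderated test of log2(value + 1) with Benjamini-Hochberg adjustment, 3183 of 12615 genes passed an adjusted p of 0.05, 1467 higher and 1716 lower in IP. The 10 largest rises among named genes that passed with separated groups were those of Ubr3 (4.02 ± 0.32), Wnt2 (3.61), Atg7 (3.34), Yeats2 (3.11), Pou3f1 (3.04 ± 0.20, adjusted p = 3.1e-06), Bahcc1 (2.87), Wfs1 (2.72 ± 0.23, adjusted p = 1.7e-05), Lefty1 (2.72), Tnrc18 (2.70) and Penk (2.67). Ubr3 encodes a ubiquitin ligase, Atg7 an enzyme of autophagy and Penk the enkephalin precursor. The 10 largest falls were those of mt-Nd6 (-5.70), mt-Nd2 (-5.62), mt-Cytb (-5.41 ± 0.26, adjusted p = 4.3e-07), mt-Nd1 (-5.22), mt-Co1 (-5.13), mt-Nd5 (-4.93), mt-Nd4 (-4.88), Dlk1 (-4.73), Ccdc171 (-4.60) and Fam163a (-4.24). The adjusted p of Cck was 9.3e-05, while Mecp2 (0.01 ± 0.18, adjusted p = 0.983) and Grm5 (0.35 ± 0.23, adjusted p = 0.273) did not pass. Each arm held 2 libraries, and no gene passed without the P37 input (lowest adjusted p = 0.268, 2315 genes at an unadjusted p under 0.05) or without the P56 input (0.246, 2158 genes). Without the P56 IP library the log2 difference of Bahcc1 was 1.79 and that of Dlk1 -2.30, and without the P37 IP library that of Dlk1 was -7.16 and that of Grm5 0.65 (limma adjusted p = 0.031). A library left alone in its arm is assumed to vary like the other arm.

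**Figure D1:**
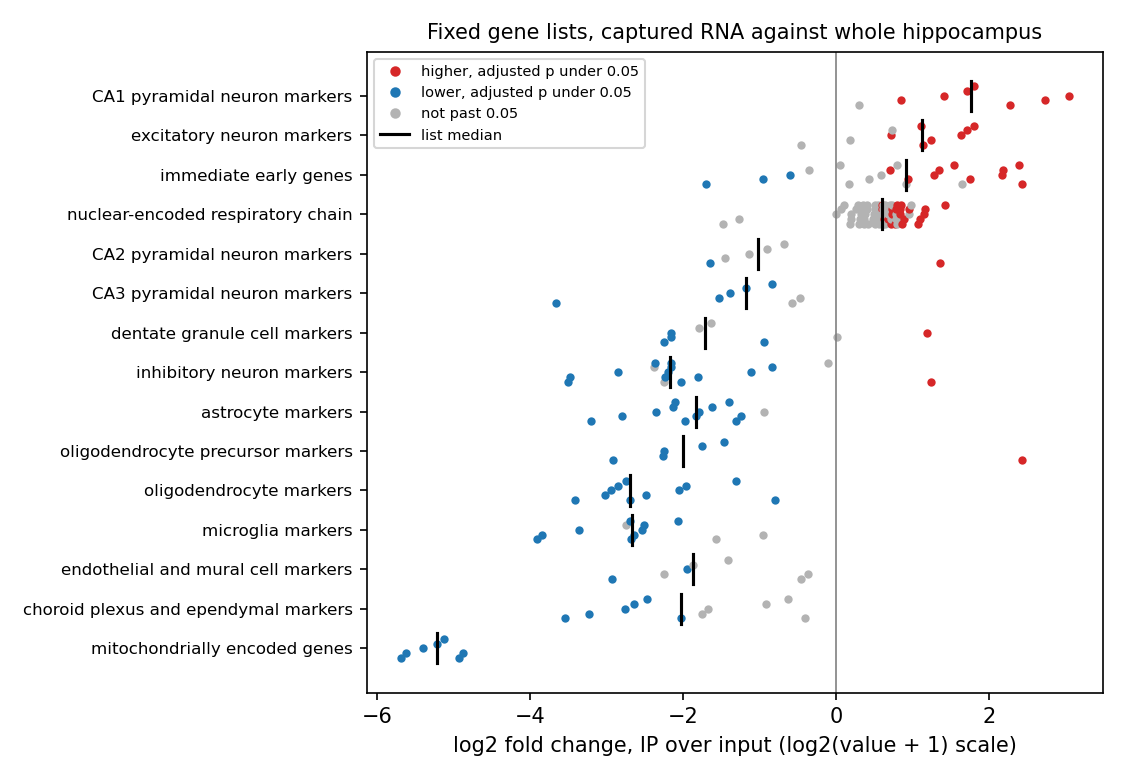
Log2 difference of IP against input for the members of 15 gene lists (points are genes, coloured where limma's adjusted p was under 0.05, bars are list medians, n = 2 libraries per arm). The CA1 list lies highest with a median of 1.76 and the mitochondrially encoded genes lowest with -5.22.

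Of the neuronal lists, those of CA1 and excitatory neurons had medians above 0 in IP and those of dentate, CA3, CA2 and inhibitory neurons below 0. Besides Pou3f1 and Wfs1, the CA1 members Fibcd1 (2.28), Neurod6 (1.81) and Satb2 (1.71) were higher in IP. The synaptic protein gene Nrgn (1.64) was among the 7 of 10 excitatory markers that were higher, with none lower (median 1.12). Neurod6 and Satb2 are on both lists. Dentate granule cell markers went the other way, with 4 of 8 lower, among them Prox1, which sets granule cell identity (-2.16), and C1ql2 (-2.25). The desmosome gene Dsp was higher (1.19). Of 7 CA3 markers, 5 were lower, including Cpne4 (-1.38) and Iyd (-3.67). Of 6 CA2 markers Rgs14 was higher (1.35) and Pcp4 lower (-1.65). Of 16 inhibitory markers, 12 were lower, among them the GABA-synthesizing enzyme gene Gad2 (-2.37), Sst (-2.24) and Lhx6 (-3.48). Calb2 was higher (1.24, limma adjusted p = 0.012; 0.0544 with the mitochondrially encoded genes left out) and was named after its value was seen. Adjusted over the list alone, 7 CA1 and 7 excitatory markers were higher, 6 dentate markers were lower and 1 higher, and 5 CA3 markers were lower. In the same way 3 CA2 markers were lower and 1 higher, and 14 inhibitory markers were lower and 1 higher. The camera test with a preset correlation called the CA1 list (adjusted p = 8.2e-06), the excitatory list (0.00052), the dentate list (0.0243), the CA3 list (0.00375) and the inhibitory list (7.5e-06), each with an adjusted p = 0.406 with an estimated correlation. The CA2 list was not called by camera (adjusted p = 0.158). With quantile normalization the excitatory median was 0.70, that of dentate markers -0.88 (-1.72 without it) and that of CA2 markers -0.63 (-1.02). Pcp4 stood at -1.07 without the P56 IP library, and Iyd at -2.16 with quantile normalization (limma adjusted p = 0.0506).

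Of the lists of non-neuronal cells, those of oligodendrocytes and astrocytes had the largest shares of members called lower. All 11 oligodendrocyte markers were lower in IP (median -2.70), among them the myelin genes Mobp (-2.74), Plp1 (-2.70) and Ermn (-3.41). Of 13 astrocyte markers, 12 were lower (median -1.84), among them the glutamate transporter gene Slc1a2 (-2.13), the water channel gene Aqp4 (-2.35) and the connexin gene Gja1 (-2.80). Of 12 microglia markers, 9 were lower (median -2.66), including C1qc (-3.92) and P2ry12 (-2.69). Of 6 oligodendrocyte precursor markers 5 were lower, including Olig1 (-2.25) and Sox10 (-2.27). Cspg4, the exception on the precursor list, was higher by 2.43 (limma adjusted p = 0.014), by 1.13 without the P56 IP library and by 3.73 without the P37 IP library. It was named after its value was seen. Of 11 choroid plexus and ependymal markers 6 were lower (median -2.03), including the transthyretin gene Ttr (-2.76) and Clic6 (-2.47). Of 7 endothelial and mural markers 2 were lower (median -1.87), including Rgs5 (-1.95). Of 4 red blood cell markers 2 were lower (median -2.50), including Hbb-bs (-2.47), a member of a family of similar genes. With quantile normalization the microglia median was -1.55, the endothelial median -0.92 and the red blood cell median -1.25. Adjusted over the list alone, 11 oligodendrocyte, 13 astrocyte, 11 microglia, 5 precursor, 6 choroid plexus, 3 endothelial and 4 red blood cell markers were lower and 1 precursor marker was higher. Camera with a preset correlation called the lists of oligodendrocytes (adjusted p = 5.7e-06), astrocytes (2.8e-07), microglia (9.4e-05), precursors (0.00445), choroid plexus (0.00035), endothelial cells (0.0246), red blood cells (0.00185) and mitochondrially encoded genes (2.4e-06), all with an adjusted p = 0.406 with an estimated correlation. Of 4 sex-linked check genes 1 was lower, 2 adjusted over the list alone (median -0.70, camera adjusted p = 0.118).

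Lists of activity and signalling genes held more members called higher than lower in IP, apart from genes reported to depend on MeCP2. Of 21 immediate early genes 10 were higher and 3 lower (11 and 3 adjusted over the list alone, median 0.91). Among them were the activity-induced transcription factor genes Egr1 (2.39), Nr4a1 (2.18) and Egr4 (2.42). Of 37 genes of mGluR5 signalling and translation control 12 were higher and 2 lower (13 and 2 adjusted over the list alone, median 0.28, or -0.08 with the mitochondrially encoded genes left out). The kinase gene Prkcg stood at 1.78, the calcium channel gene Itpr1 at 1.29, Arc at 1.35 and the kinase gene Mapk3 at -1.33. Of 29 mRNAs known as targets of FMRP, a translation regulator, 15 were higher and 2 lower (16 and 2 adjusted over the list alone, median 0.68). The ankyrin genes Ank2 stood at 2.06 and Ank3 at 1.92, Syngap1 at 1.29 and Pclo at -0.91. Of 20 genes reported to depend on MeCP2 7 were lower and 2 higher (10 and 2 adjusted over the list alone, median -0.98), among them Sst, Id3 (-2.91) and Mef2c (-1.23). With quantile normalization the FMRP median was 0.17, the mGluR5 median 0.12 and the MeCP2-dependent median -0.50. Serpina3n, a serine protease inhibitor on the interferon list, was higher (1.69). Camera with a preset correlation called the immediate early list (adjusted p = 0.00127), the mGluR5 list (0.0058) and the MeCP2-dependent list (0.0243), each with an adjusted p = 0.406 with an estimated correlation, and the FMRP list (0.00052; 0.553 with an estimated correlation). With the mitochondrially encoded genes left out and libraries scaled to their totals, the median of all genes shifted by -0.37 and 3335 genes were called in IP against input, 15.7% of them higher, against 46.1% of the 3183. The mGluR5 median then lay above the shifted median of all genes, as did those of the FMRP (0.32) and immediate early (0.57) lists.

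Among lists of cell machinery, 21 of 75 nuclear-encoded respiratory chain genes were higher in IP and none lower (30 and 0 adjusted over the list alone, median 0.60), including the complex I genes Ndufa5 (1.43) and Ndufb5 (1.07). Of 73 ribosomal protein genes 2 were higher (1 adjusted over the list alone, median 0.16, or -0.20 with the mitochondrially encoded genes left out, including Rpl15 at 1.39). Of 61 translation factor genes 9 were higher and 4 lower (8 and 4 adjusted over the list alone, median 0.23, or -0.12 with the mitochondrially encoded genes left out), including Eef1a2 (1.04) and the translation repressor gene Eif4ebp3 (-4.37). Of 59 protocadherins 5 were higher and 2 lower (3 and 2 adjusted over the list alone, median 0.42), with Pcdhga2 at 2.58 and Pcdh15 at -2.88. Of 27 histone genes 4 were higher and 1 lower (3 and 1 adjusted over the list alone, median 0.45). Of 19 collagens 4 were lower (6 adjusted over the list alone, median -0.85), with Col23a1 at -3.24, or -1.93 without the P56 IP library. Quantile normalization changed the medians of ribosomal proteins (0.35), protocadherins (1.05), histones (0.77) and collagens (-0.30). Leaving out the mitochondrially encoded genes, which shifts all genes by -0.37, gave 0.25 for the respiratory chain and 0.06 for protocadherins and for histones. Protocadherins and histones are families of similar genes, and how reads matching several members were assigned is not given in the sources used here. Camera with a preset correlation called the respiratory chain (adjusted p = 2.8e-07; 0.546 with an estimated correlation), the ribosomal proteins (0.0243; 0.783), the translation factors (0.0459; 0.509), the protocadherins (0.0161; 0.553), the histones (0.0161; 0.406) and the collagens (0.0221; 0.406). The number after each semicolon is camera's adjusted p with an estimated correlation.

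The other lists were not called by camera in IP against input. Of 15 ionotropic glutamate receptors, 2 were higher, among them the NMDA receptor gene Grin1 (1.51), and 6 lower, among them Gria4 (-1.91) and Grik3 (-1.40). Of these 3 and 6 passed adjusted over the list alone, and the median was 0.11 where the mean was -0.58 (camera adjusted p = 0.42). Of 18 potassium channels 3 were higher, including Kcnd2 (1.42), and 7 lower, including Kcnd3 (-1.75; 5 and 9 adjusted over the list alone, median -0.23, adjusted p = 0.384). Of 30 sodium and calcium channels 9 were higher, including Cacnb1 (1.69), and 9 lower (9 and 9 adjusted over the list alone; median 0.21, mean -0.09, adjusted p = 0.642). Of 12 GABA-A subunits 1 was higher, Gabra5 (1.25), and 2 lower (1 and 2 adjusted over the list alone, median -0.22, adjusted p = 0.596). Of 19 synaptic vesicle genes 6 were higher and 2 lower (7 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.273). Stx1a stood at 1.13 and Syn1 at 0.97, the latter with an adjusted p = 0.14 in limma after quantile normalization. Of 18 genes of the unfolded protein and heat shock response 3 were higher (3 adjusted over the list alone, median 0.32), including Hspa8 (0.91). The log2 fold change of Hspa8, IP against input, had a limma adjusted p = 0.0558 with the mitochondrially encoded genes left out. Camera's adjusted p of this list was 0.0561, and 0.0476 with age as a block (0.549 with the block and an estimated correlation). Of 15 corepressor partners of MeCP2 3 were higher, including Ncor2 (1.12), and 2 lower (3 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.273). Glucocorticoid response genes (16, with 3 higher including Klf9 at 1.12 and 5 lower including Mt2 at -2.11; 3 and 5 adjusted over the list alone; median -0.05, adjusted p = 0.661) were not called. Neither were cholesterol synthesis genes (20, with 2 lower; 0 adjusted over the list alone; median -0.04, adjusted p = 0.903) or interferon genes (12, with 1 higher and 2 lower; 1 and 2 adjusted over the list alone; median -0.48, adjusted p = 0.301). With quantile normalization the corepressor median was 0.15 and the GABA-A median -0.40. It turned the medians of the vesicle (-0.39), glutamate receptor (-0.44), sodium and calcium channel (-0.21), glucocorticoid (0.05), cholesterol (0.06) and interferon (0.16) lists. Leaving out the mitochondrially encoded genes, with its shift of all genes by -0.37, turned those of the vesicle (-0.20), glutamate receptor (-0.24), sodium and calcium channel (-0.15), corepressor (-0.05) and heat shock (-0.04) lists.

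Knockout and wild-type IP libraries were compared to find what the loss of Mecp2 changed in the captured RNA. Mecp2 itself, the targeted gene, was lower in each knockout library. It stood at 72.2 normalized reads at P37, 49.6 at P41, 163 at P50 and 316 at P56, against 3082, 3515, 3678 and 3350 in the wild types. These knockout levels were 2.12%, 1.46%, 4.78% and 9.28% of the wild-type mean. The targeted allele removes most of the coding sequence, and values per gene do not separate the kept exons from the deleted ones. Of the genes higher in knockouts, Net1 alone passed in limma without a block, and it encodes an activator of the small GTPase RhoA. It stood at 859 ± 95.5 in knockouts and 319 ± 108 in wild types (mean ± SD, n = 4 libraries each). Markers of CA1 neurons had a median log2 difference of -0.23, and those of oligodendrocytes, astrocytes and dentate granule cells of 0.72, 0.42 and 0.75. Camera called these 4 lists with a preset correlation, and with an estimated correlation none passed (adjusted p = 0.603 for CA1 and 0.687 for the others).

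Of 11902 genes, 2 passed an adjusted p of 0.05 in limma and 759 an unadjusted p of 0.05. Mecp2 (chromosome X, 74026592 to 74135363, GRCm38) fell by 4.85 ± 0.38 on the log2 scale (limma adjusted p = 2.5e-06, lower in 4 of 4 knockouts) and Net1 (chromosome 13, 3882018 to 3918220) rose by 1.47 ± 0.22 (limma adjusted p = 0.014). EdgeR's quasi-likelihood test on the recovered reads called 2 genes as well, and DESeq2 29, of which 24 were higher and 5 lower. Net1 no longer passed in limma when the library of the P41 knockout (adjusted p = 0.0735), the P56 wild type (0.0749), the P50 wild type (0.0865), the P41 wild type (0.101) or the P50 knockout (0.152) was left out. Its log2 difference stayed between 1.34 and 1.68 with any 1 library left out. Cck (-0.19 ± 0.22, adjusted p = 0.917) and Grm5 (0.02 ± 0.19, adjusted p = 0.993) did not pass.

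Among genes that did not pass, those with fully separated groups and the smallest p-values are given as values. Irak1 is a kinase gene of interleukin 1 receptor signalling. It lies on the same strand of chromosome X as Mecp2, and its start lies 2674 bp beyond the end of Mecp2. Irak1 stood at 599.8 ± 141 in knockouts and 260.9 ± 74.5 in wild types (log2 difference 1.22 ± 0.25, limma adjusted p = 0.423). The myelin gene Mobp differed by 1.07 ± 0.22, Nfkb1, a subunit of NF-kappa B, by 1.88 ± 0.43 and the spliceosome gene Snrnp70 by 0.98 ± 0.24. On the lower side were Serpina3n (451.5 ± 84.8 against 807 ± 117, log2 difference -0.85 ± 0.19), the histone RNA processing gene Lsm11 (-0.89), the retinoic acid receptor gene Rara (-0.81) and the CA1 marker Fibcd1 (-0.61 ± 0.15).

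With the age of the animals as a block, 25 genes passed in limma, 20 higher and 5 lower in knockouts. Those higher included the spectrin genes Sptan1 (0.60) and Sptb (0.68), the linker genes Plec (0.69) and Dst (0.62), Ppp1r9a (0.72), which encodes the actin-binding protein neurabin, the filamin gene Flnb (1.00), the dynein heavy chain gene Dync1h1 (0.80) and the myosin gene Myh10 (0.57). They also included the myelin genes Mbp (0.72) and Mobp, Irak1, Net1, Lrp1b (1.08), Snhg11 (1.39), Fras1 (1.32), Gprasp1 (0.76), Mapk8ip2 (0.63), Lmo7 (0.73), Sema5a (1.00) and Tenm1 (0.89). Besides Mecp2, those lower were Wipf3 (-0.46), the calcium sensor gene Hpcal4 (-0.50), Serpina3n and the calmodulin gene Calm1 (-0.39). The fit with the block was not run with 1 library left out, so the following log2 differences come from the unblocked fit. Without the P56 knockout those of Dst (0.39), Dync1h1 (0.47), Myh10 (0.33), Gprasp1 (0.46) and Mapk8ip2 (0.40) were smaller. So were those of Sptan1 (0.37) and Mapk8ip2 (0.41) without the P37 wild type. Without the P37 knockout those of Sptan1 (0.94), Sptb (1.03), Ppp1r9a (1.10) and Mapk8ip2 (1.03) were larger. EdgeR with the block called 10 genes (8 higher, 2 lower) and DESeq2 173 (139 higher, 34 lower). With the trend over transcript length taken out as well, limma with the block called 10 (5 higher, 5 lower).

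**Figure D2:**
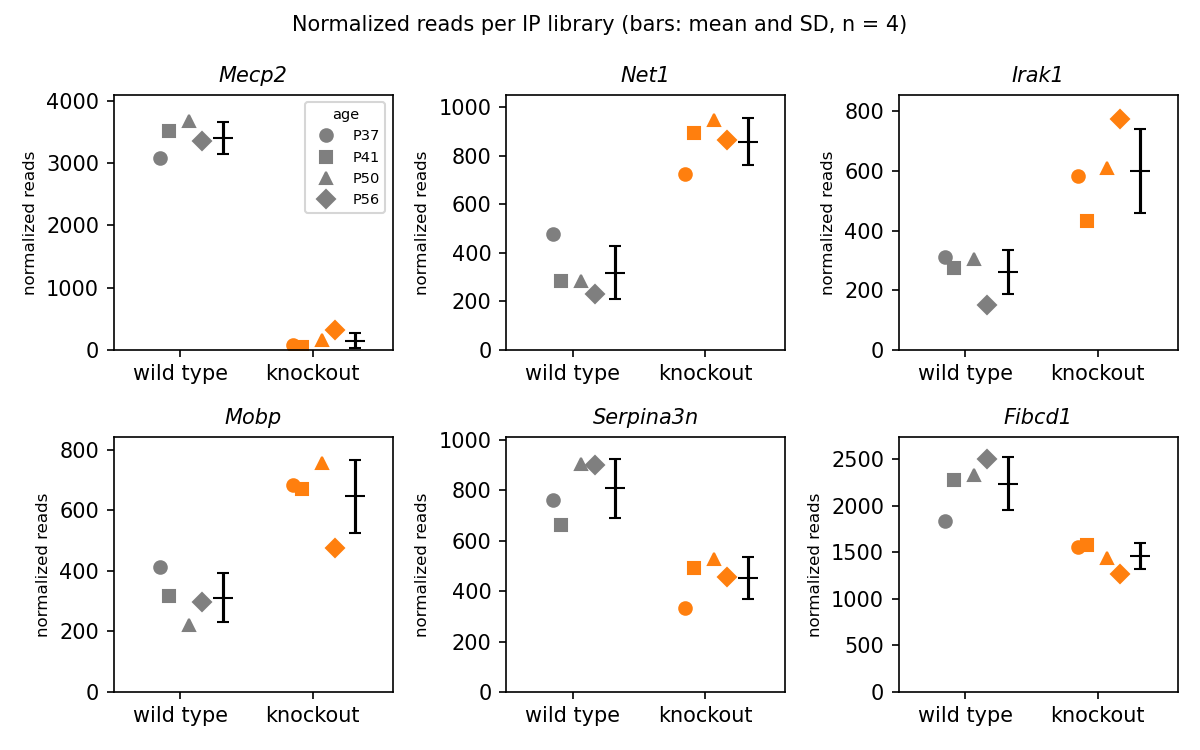
Normalized reads per IP library of 6 genes in wild types and knockouts, with group means and SD (n = 4 libraries per genotype). Mecp2 lies between 49.6 and 316 in knockouts and between 3082 and 3678 in wild types, and Net1 is higher in every knockout library than in every wild-type library.

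Cell type lists lay on both sides of 0 in knockouts against wild types. All 8 CA1 markers lay below 0 (median -0.23), among them Fibcd1 and Wfs1 (-0.43 ± 0.16). All 11 oligodendrocyte markers lay above 0 (median 0.72), among them Mobp, Mbp, Mag (1.02 ± 0.36) and Cnp (0.45 ± 0.17). Astrocyte markers had a median of 0.42, with Gja1 at 1.15 ± 0.37, Slc1a2 at 0.53 ± 0.20 (0.29 without the P56 knockout) and Sox9 at 0.76 ± 0.34. Dentate markers had a median of 0.75, with Plk5 at 1.44 ± 0.61 and Npnt at 0.82 ± 0.44. Inhibitory markers had a median of 0.45, with Reln at 0.80 ± 0.30 and the neuropeptide gene Npy at 1.16 ± 0.57. Collagens had a median of 0.63, with Col6a1 at 2.44 ± 0.66, and FMRP targets of 0.15, with Dync1h1 and the microtubule gene Map1b (0.48 ± 0.18). Without the P56 knockout Map1b stood at 0.27 and Dync1h1 at 0.47, and without the P56 wild type Wfs1 stood at -0.27 and Npnt at 0.54.

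No member of these 7 lists passed limma's test over all genes. Adjusted over the list alone, 6 oligodendrocyte markers and 1 collagen were higher, 1 CA1 marker was lower and no dentate, astrocyte, inhibitory or FMRP list member passed. Camera with a preset correlation called the lists of CA1 (lower, adjusted p = 0.0025; 0.603 with an estimated correlation), oligodendrocytes (2.4e-06; 0.687), astrocytes (0.0025; 0.687), dentate cells (0.0104; 0.687), inhibitory neurons (0.0443; 0.707), collagens (0.0066; 0.687) and FMRP targets (0.0232; 0.713). All but CA1 were higher, and the number after each semicolon is the adjusted p with an estimated correlation. With the age block camera no longer called the inhibitory list (adjusted p = 0.0572). It then called endothelial markers (higher, median 0.78, adjusted p = 0.0402 against 0.137 unblocked) and respiratory chain genes (lower, median -0.10, 0.0136 against 0.102). None held with an estimated correlation (lowest adjusted p = 0.659), and limma's fry, which asks whether a list moves one way on balance, called none (lowest adjusted p = 0.0902). On other lists, over the list alone, Irak1 was higher among genes reported to depend on MeCP2, Nfkb1 was higher and Serpina3n lower among interferon genes, and no member of the remaining lists passed. The mGluR5 list had a median of 0.05 and the immediate early list of 0.01, or below 0 with quantile normalization. As mean log2 level per library, the CA1 score was lower in knockouts by -0.30 ± 0.06 (SE, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow, adjusted p = 0.248). The oligodendrocyte score was higher by 0.70 ± 0.27, the dentate score by 0.72 ± 0.26 and the inhibitory score by 0.39 ± 0.19 (exact p = 0.0857 each). These SEs and permutations did not pair libraries by age. At every age the oligodendrocyte, dentate and inhibitory scores were higher, and the CA1 score lower, in the knockout than in the wild type of that age. The oligodendrocyte median was 0.07 at P37, 0.86 at P41, 1.04 at P50 and 0.66 at P56. The mitochondrially encoded score differed by 0.34 ± 0.52 (exact p = 0.543) and the choroid plexus score by -1.14 ± 0.94 (exact p = 0.286). The choroid plexus score rested on the P56 knockout, without which it differed by -0.35 ± 0.63. The mitochondrially encoded score differed by 0.01 without the P50 wild type, 0.05 without the P41 knockout and up to 0.58 without the P37 knockout, and the inhibitory score by 0.24 without the P56 knockout.

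**Figure D3:**
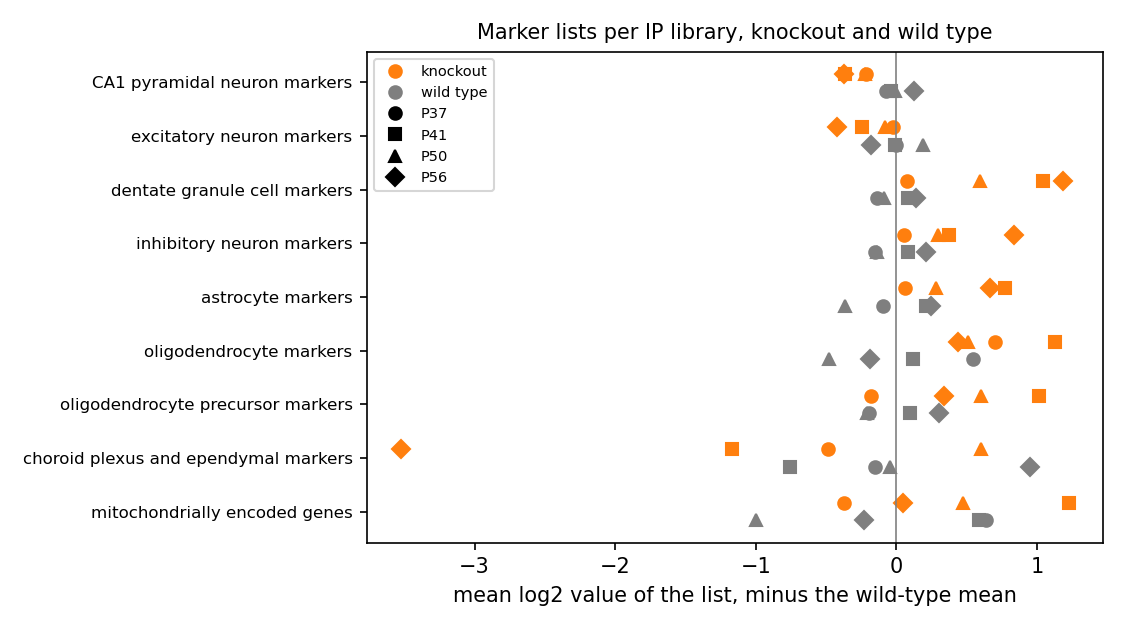
Mean log2 level of cell type lists per IP library, minus the wild-type mean (points are libraries, shapes are ages, n = 4 per genotype). The CA1 score is lower in knockouts by -0.30 with no overlap between the genotypes, and the oligodendrocyte score is higher by 0.70.

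Whether the genotype difference changed as the animals aged was tested by setting P50 and P56 against P37 and P41. Mecp2 differed between age classes by 1.81 ± 0.42 on the log2 scale, with higher knockout levels at P50 and P56, and the histone gene Hist1h4d by -1.75 ± 0.32. In limma's interaction test 0 of 11902 genes passed and 495 had an unadjusted p under 0.05 (lowest adjusted p = 0.705; 0.976 for Mecp2). DESeq2 called those 2 genes (adjusted p = 0.031 for Mecp2 and 0.0077 for Hist1h4d). Both age classes held 2 libraries per genotype. Without the P50 knockout library, which leaves the P56 knockout alone in its group and assumed to vary like the others, limma called 1 gene, Ttr (-7.33). Ttr stood at 12.7 normalized reads in the P56 knockout and between 1518 and 5101 in the other 7 libraries, so this call rests on 1 library.

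The genes that differed by genotype were then placed on the IP and input scale, to see whether they belonged to the captured cells. For this the knockouts were set against the P41 and P50 wild types alone, which the IP and input comparison did not use, and the 100 genes with the smallest p in each direction were taken. The 99 genes of the higher set that could be placed had a median IP against input difference of -0.82, below all 10000 random lists of like expression (central 95% of -0.31 to 0.08). Of the 99, 78 were negative, 37 were called depleted and 1 was called enriched. Genes lower in knockouts were not set apart, with a median of 0.14 over 98 genes (percentile 62.9, random lists -0.04 to 0.26), 11 called depleted and 19 enriched. Random lists treat genes as independent; of the 15 splits of the 6 libraries, which allow no share under 0.05, 2 gave a rho as far from 0, the real one included. The other of these was 0.325, in the opposite direction, and the most negative other rho was -0.197. Across 12179 genes, which are not independent replicates, the knockout difference and the IP difference had a Spearman rho of -0.211, or -0.128 without the P56 knockout. The medians moved to -0.38 and 0.42 without the P37 knockout and to -0.63 and 0.24 without the P41 knockout. That of the lower genes moved to 0.03 without the P41 wild type and 0.22 without the P50 wild type. With all 4 wild types the medians were -1.09 and 0.55. The P37 and P56 wild-type IP libraries then enter both comparisons, which by itself drives the medians apart, so these values add no support.

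Long genes have been described as raised in the brain without MeCP2, so length was set against the genotype difference. Genes over 100 kb (2018 of 11872, among them Lrp1b, Fras1 and Dst, which passed with the age block) had a median 0.10 above the rest on the log2 scale. Of the 35 splits of the libraries, 12 gave a difference as far from 0, the real one included (highest other 0.213). For the rho with genomic length given below, 21 of 35 lay as far from 0 (highest other 0.339). Chance cannot be excluded for either. The relation was closer with the length of the transcript than with that of the gene. Across genes, which are not independent replicates, Spearman's rho was 0.196 with transcript length, 0.137 with genomic length and 0.024 with genomic length given transcript length. Of the 20 genes higher in knockouts with the age block the median transcript was 8559 bases, of the 5 lower ones 4516, and of all genes 3639. The relation with transcript length was -0.05 at P37, 0.01 at P41, 0.25 at P50 and 0.23 at P56. Without the P56 knockout library the rho was 0.03 with transcript length and -0.002 with genomic length and the difference over 100 kb was 0.03. Without the P50 knockout the values were 0.11, 0.07 and 0.07, without the P37 wild type 0.12 and 0.08 for the 2 rho values, and without the P37 knockout 0.29, 0.21 and 0.16. The smallest and largest of the differences over 100 kb at single ages were -0.007 (P37) and 0.24 (P56).

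**Figure D4:**
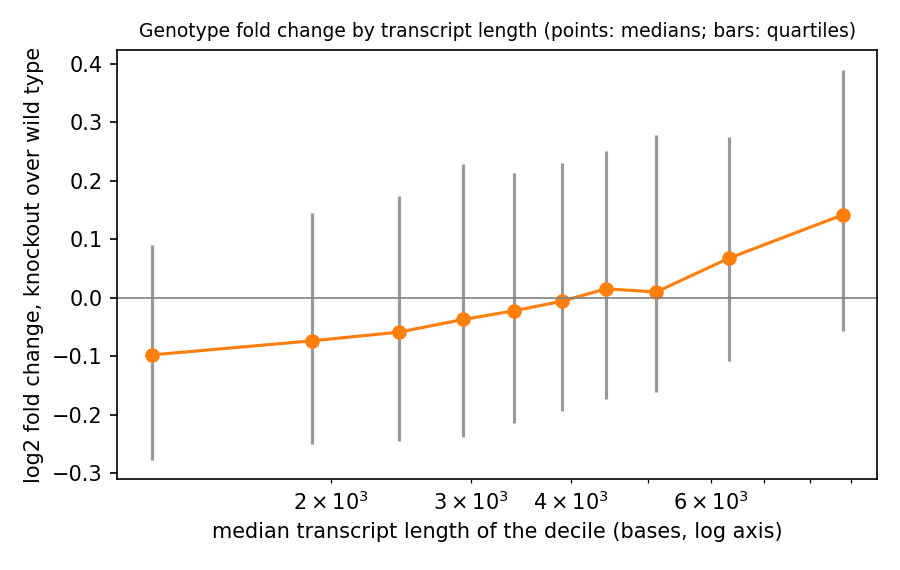
Log2 difference of knockouts against wild types by decile of transcript length (points are medians, bars the quartiles, over 1187 or 1188 genes each). The median rises from -0.10 in the shortest decile to 0.14 in the longest.

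CTEP and vehicle were compared in knockouts to see what the drug changed. No gene could be named as raised or lowered by it. Grm5, which encodes the receptor the drug acts on, stood at 1274 ± 462 with CTEP (mean ± SD, n = 3) and 1156 ± 145 with vehicle (n = 2), and Cck at 17341 ± 8630 and 14796.5 ± 4201. Arc, an immediate early gene translated after mGluR5 activation, differed by -0.60 ± 0.50 on the log2 scale and the growth kinase gene Mtor by -0.34 ± 0.30. The difference of Arc was -0.009 without the first of the P57 CTEP libraries, -0.02 without the P60 vehicle, -1.17 without the P60 CTEP and -1.19 without the P57 vehicle library, and that of Mtor was -0.51 without the P60 CTEP library. Mecp2, the deleted gene, read 131 with vehicle and 25.9 with CTEP at P60, and 5.34 with vehicle and 6.60 and 15.1 with CTEP at P57.

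In limma 0 of 12376 genes passed, 139 had an unadjusted p under 0.05 and every adjusted p rounded to 1.00. EdgeR called 0 genes (142 at an unadjusted p under 0.05). DESeq2 called 4, Tex14, Kbtbd13 and Cpn2 higher and 1700014D04Rik lower, each with reads in 1 library alone, and 0 with the age block (438 at an unadjusted p under 0.05). Separated groups with the smallest p-values were found, higher with CTEP, for the DNA polymerase gene Polm (2.60 ± 0.80), Mtap (2.24 ± 0.75), the Wnt signalling gene Rspo2 (1.77 ± 0.62), Zfp940 (1.27 ± 0.45) and Ttl (1.01 ± 0.36). On the lower side were Chrd (-2.06 ± 0.69), Nme4 (-2.90 ± 1.02), Arhgef10 (-1.90 ± 0.68), Smox (-1.92 ± 0.70) and Gprasp2 (-1.16 ± 0.43). Without the P57 vehicle library Polm stood at 1.49, Mtap at 1.23 and Arhgef10 at -1.16, and without the second of the P57 CTEP libraries Gprasp2 stood at -0.77. With 3 against 2 libraries the test recovered 56.1% of simulated 4-fold changes and 3.03% of 2-fold changes, so smaller changes were mostly not detectable.

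No gene list passed in this comparison (lowest camera adjusted p = 0.119), and no member of any list passed adjusted over the list alone. The lists with the smallest camera p had medians below 0 with CTEP: collagens (-0.59, adjusted p = 0.119), choroid plexus markers (-1.77, adjusted p = 0.119, with Clic6 at -2.58 ± 1.49), astrocyte markers (-0.38, adjusted p = 0.119, with Aqp4 at -0.78 ± 0.79) and oligodendrocyte markers (-0.34, adjusted p = 0.143, with Cnp at -0.85 ± 0.43). The mGluR5 list had a median of 0.02, FMRP targets of -0.12, CA1 markers of -0.003 and immediate early genes of -0.20, with Egr2 at -2.26 ± 1.28. Without the first of the P57 CTEP libraries Egr2 stood at -0.25, and without the P60 CTEP library at -3.58. Without the second of the P57 CTEP libraries Clic6 stood at -0.89, Cnp at -0.40 and Aqp4 at -0.17. Aqp4 stood at -0.02 without the P60 vehicle, -1.28 without the P60 CTEP and -1.55 without the P57 vehicle library, which also left Clic6 at -1.65. The choroid plexus gene Ttr read 0 in 1 of the 2 P57 CTEP libraries and between 425 and 3345 in the other 4.

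Whether CTEP moved the genotype differences back toward wild type was tested on the 2 sets of log2 differences, which share no library. The 100 genes with the smallest p among those higher in knockouts (99 tested here) had a median of -0.23 with CTEP, 64 below and 35 above 0, and the 100 lower ones a median of -0.04, 58 below and 42 above 0. Snhg11, which was higher in knockouts with the age block, stood at -1.09 ± 0.45 with CTEP and Flnb at -0.95 ± 0.58, while Net1 stood at 0.32 ± 0.31, Irak1 at -0.07 ± 0.35, Mobp at -0.50 ± 0.42, Nfkb1 at 1.20 ± 0.85 and Serpina3n at -0.44 ± 0.35. Across 11714 genes, which are not independent replicates, Spearman's rho was -0.066 and Pearson's r -0.055. Camera with a preset correlation gave p = 0.030 for the higher set (0.486 with an estimated correlation; 0.115 with the age block) and p = 0.513 for the lower set (0.425 with an estimated correlation). Of the 10 splits of the 5 drug libraries into 3 and 2, 3 gave a rho at or below the real one, the real one included (range -0.107 to 0.0993). The lowest set P60 against P57. Same-age drug libraries deviated together (correlations of 0.302 at P60 and of 0.124 and 0.164 at P57). The deviations of the 2 vehicle libraries mirror each other, so these correlations are tied to one another and are not separate observations. The 6 splits with 1 library of each age in the group of 2 were looked at after the others. Of these, 2 gave a rho at or below the real one, the real one included (range -0.0898 to 0.0465). Neither count of splits allows a share under 0.05. Without the P60 vehicle library the rho was 0.0216 and the higher set's median 0.05, and without the P57 vehicle library that median was -0.60. With the higher set taken from the genotype fit with age as a block the median was -0.45. That set is smaller, as it holds the 20 genes called higher there, whose median transcript was 8559 bases. Genes called lower in that fit did not rise with CTEP. Besides Mecp2, Wipf3 stood at -0.11, Hpcal4 at -0.15, Serpina3n at -0.44 and Calm1 at -0.006.

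**Figure D5:**
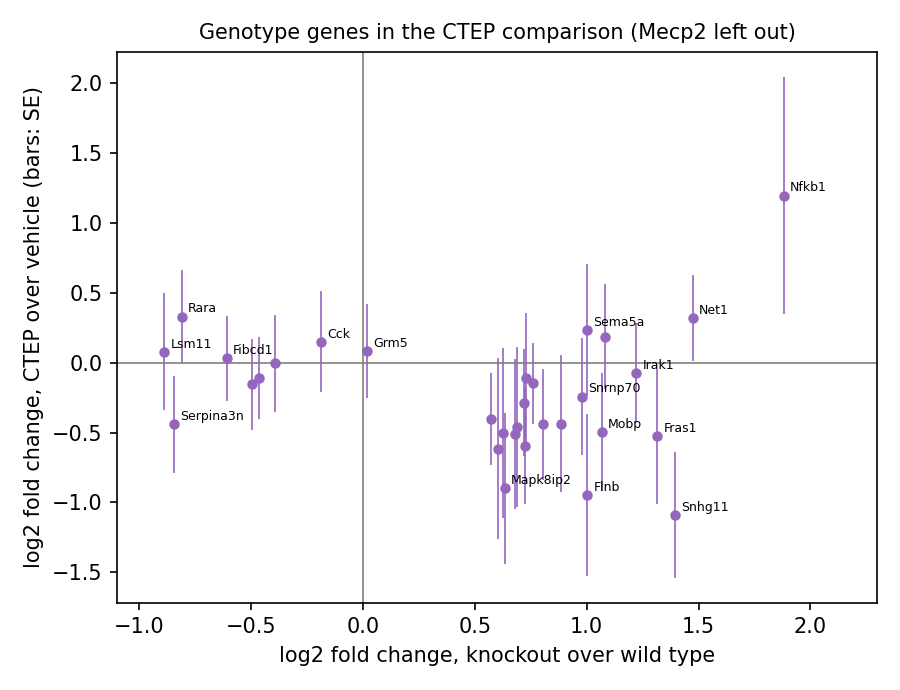
Log2 difference of CTEP against vehicle in knockouts, with SE bars, plotted against the log2 difference of knockouts against wild types, for the genes named in the genotype comparison without Mecp2 (points are genes). Snhg11 lies lowest on the drug axis at -1.09 and Nfkb1 highest at 1.20.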

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

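Among the 8 tests given here, the count of genotype splits and the 3 tests on length were written before their results were seen, and the 3 tests on capture and the test of admixture were chosen after. Dixon's test for an outlying value was run on 114 groups of 4 values. No library stood apart from the other 3 of its group, where chance would place about 1 in 20. With 4 values that test misses all but extreme gaps, so it does not show that the libraries of a group were alike. The choroid plexus score, for example, was 2.81 in the P56 knockout and between 5.17 and 6.94 in the other knockouts. The smaller input, vehicle and CTEP groups were not examined in this way.

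The number of genes called between genotypes, 2 in limma, was met or passed by 3 of the 35 splits of the 8 libraries into 4 and 4, the real one included, so chance cannot be excluded for this count. The highest other split gave 37 genes, which points to a structure of the samples. It set the P37 knockout with the P37, P41 and P50 wild types against the rest. Of its 37 genes, 10 were among the 25 called with age as a block. In that split 33 of the 37 were lower in the group with the P37 knockout, and the median transcript was 7791 bases. The 20 genes higher in knockouts with the block likewise had long transcripts (median 8559 bases). Among the 8 splits that part all same-age pairs, which are too few for a share under 0.05, the real one gave 25 genes with the block and the highest other 0.

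The set of 99 genes higher in knockouts had a median of -0.82 in IP against input, with 37 called depleted, and a first candidate explanation is more RNA of unpurified tissue in the knockout IP libraries. A share of 11.0% (95% limits 5.9% to 16.8%) would account for the 10 other depleted lists within 2 SE, but it was fitted to those same lists. The limits treat the lists as independent, though all were scored in the same libraries, so they are likely too narrow. That share needs the mitochondrially encoded genes to be higher by 2.32 on the log2 scale, or 1.65 at the lower limit. Their measured mean difference was 0.344 ± 0.52 (SE), which argues against it. With any 1 library left out and the share fitted anew (7.8% to 16.5%) that difference ran from 0.01 to 0.58. It lay between -4.99 and -2.48 SE from what the best-fitting share needed. Against the lower limit of the share the gap was smaller. Without the P56 knockout that limit needed 1.20, and 0.44 ± 0.60 was measured, which is within 2 SE. The same held without the P50 knockout (1.44 against 0.30 ± 0.62), the P41 wild type or the P37 wild type. The evidence against this explanation therefore weakens when 1 of these libraries is left out. RNA of other cell types without their mitochondria may account for the pattern: 7 of the 10 lists lay above 0, and CA3, CA2 and choroid plexus markers, which did not, lay within 2 SE of what that share needs, so this stays open, as does a change of expression in the knockout cells themselves, which was not tested. The 15 splits of the 6 libraries are too few for a share under 0.05; the real rho was -0.211 and 2 splits lay as far from 0, the real one included, the other being 0.325 in the opposite direction and the most negative other -0.197.

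The knockout difference had a rho of 0.196 with transcript length over all ages, though of -0.05 at P37 and 0.01 at P41. With the trend over transcript length taken out of each library in the fit with age as a block, 8 of the 25 calls stayed, and the median absolute log2 difference of the 25 went from 0.76 (median SE 0.137) to 0.64 (0.124), so a trend over length may account for part of the calls. Taking out the trend over genomic length also left 8 of the 25, and that over GC content 18, so the loss of calls does not single out transcript length. Given transcript length, 30 of 35 splits lay as far from 0 as the real rho of 0.024 with genomic length (highest other 0.123), and for transcript length 17 of 35 lay as far (highest other 0.416), so chance cannot be excluded for either. An effect of genotype on long transcripts stays open, and the integrity of each library's RNA is not given in the sources used here.

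Mecp2 reads were most numerous in the P56 knockout, with 323 reads or 9.28% of the wild-type mean. Admixture of wild-type RNA at that share would have brought Ttr to at least 188 normalized reads, given the lowest wild-type Ttr of 2025. Ttr stood at 12.7 in the P56 knockout (upper 95% limit for counting error 21.8). This argues against admixture of RNA with Ttr levels like those of the wild types in the genotype comparison. Ttr differed widely between IP libraries, however, and read 0 in the second of the P57 CTEP libraries. Admixture of wild-type RNA low in Ttr therefore stays open. Exons that the targeted allele keeps could also give reads. Mecp2 ran from 49.6 to 316 in the knockouts of the genotype comparison and from 5.34 to 131 in those given CTEP or vehicle. That spread argues against kept exons read at a like level in every knockout. Values per gene do not show which exons were read.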

How the results depend on the processing

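The edgeR tests, the DESeq2 tests with a block, the fit with the transcript length trend taken out, and leaving out a library (captured genes, marker scores and the share of unpurified RNA) or using TMM scaling for captured genes were chosen after seeing the data. Count tests of IP against input were not run. The IP against input calls ranged from 2632 to 4241 over the alternative fits, and from 0 (without either input) to 4276 (without the P37 IP library); the lone library is then assumed to vary like the other arm. Of the named genes, 4 calls under other fits and 172 with 1 library left out no longer passed in that comparison. The log2 fold change of Mecp2, IP against input, turned to -0.45 with quantile normalization, -0.0195 with log2 CPM and -0.35 with mitochondrially encoded genes left out, and spanned -0.0588 to 0.0725 with 1 library left out; the log2 fold change of Grm5, IP against input, turned to -0.0093 with mitochondrially encoded genes left out. That alternative also replaces size factors by library totals and shifts the median of all genes by -0.37, so the changes of sign under it follow from that shift. Between genotypes 2 genes were called; 25 with the age block, 29 by DESeq2, 10 by edgeR with the block, 173 by DESeq2 with the block, 10 with the block and the transcript length trend taken out, and 1 to 2 with 1 library left out. There Grm5 turned to -0.14 with the block and the trend taken out and spanned -0.087 to 0.14 with 1 library left out, and Cck spanned -0.35 to 0.0394. The genotype effect by age had 2 calls in DESeq2 and 0 to 1 with 1 library left out. For CTEP DESeq2 called 4 genes, each read in 1 library; with 1 library left out Mecp2 spanned -3.14 to 1.23, Cck -0.23 to 0.44 and Grm5 -0.19 to 0.33. In the reversal test, leaving out 1 library moved rho from -0.128 to 0.0216, the median of the higher genes from -0.60 to 0.0548 and that of the lower genes from -0.11 to -0.00855. For captured genes the medians of the higher and lower genes spanned -0.87 to -0.38 and 0.0282 to 0.42 with 1 library left out. They were -1.09 and 0.55 with all 4 wild types, where libraries shared by both comparisons by themselves drive the medians apart. None of the 34 lists of the drug comparison passed under any alternative run. All 23 IP and all 7 genotype list calls were lost with an estimated correlation. In IP against input, which had the fewest libraries, that test can hardly pass, and even the mitochondrially encoded genes (median -5.22 in IP) failed it. The IP losses therefore do not tell which lists changed. The genotype comparison had more libraries, so its losses are less readily set aside, and its 7 list calls rest on the preset correlation. Fry, which does not compare a list with other genes, did not call 12 of the 23 IP lists (adjusted p = 0.0563 to 0.590 in limma) or any of the 7 genotype lists; it called 1 list that camera did not, the sex-linked genes in IP (0.0366). The cause was not tested for any of these. Depth limits low genes: 3 reads equal up to 4.81 normalized reads.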

Other observations

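The neighbours of Mecp2 on chromosome X were looked at after Irak1 had been seen, and no test of an explanation was made here. Irak1, 2674 bp away on the same strand, had the smallest p among them and was higher in knockouts by 1.22. The other 25 genes tested within 500 kb had a median log2 difference of 0.02 between knockouts and wild types and a range of -0.19 to 1.65. The axon guidance receptor gene Plxnb3 lay highest at 1.65, the kinase gene Pnck at 0.67 and the transcription cofactor gene Hcfc1 at 0.38, and none of them passed limma's adjusted p of 0.05.

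Genes seen in 1 library alone were rare. In the genotype libraries 2 genes had at least 50 normalized reads in 1 library and 0 in all others, both in the P56 wild type, among them the potassium channel gene Kcnj8 at 54.7. In the drug table there were 9, and in the IP table none. Read at 0 in 1 library and at 50 or more elsewhere were 2 genes of the drug table, Ttr among them, and Atp10b in the P56 IP library.

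The drug libraries of P57 had 13590962 to 16526396 reads and between 12920 and 13151 genes with a read, while those of P60 had 7853821 and 8298749 reads and 14036 and 13842 genes. Age and library complexity cannot be told apart in this set.

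The order of genes in the authors' genotype table was close to that of the fit with age as a block, a check made after both fits were seen. Of the table's first 100 genes, 95 were among the 100 smallest p-values of that fit in limma, against 50 without the block, and 96 against 44 in DESeq2.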
